A study of Homo sapiens with 24 samples.

How the data were processed

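The analysis used deposited processed tables of 24 RNA-seq libraries from 2 cell lines, with no reads aligned here. Per the labels, cells received 300 pmol of scramble siRNA (siCtrl) or 100 pmol each of 3 siRNAs against lnc-RAINY (siPool), 8 Gy or none 24 h later, and 72 h of recovery. Per the submitters' processing notes, reads were handled with Subread and DESeq2 on hg38, and the versions are not given in the sources used here. Ribosomal RNA was depleted in the libraries per the labels.

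The deposited H460 table held a count per gene for 28395 genes, of which 27745 were matched to the reference by their gene numbers. The deposited H820 table was labelled RPKM, and its values for 20468 genes were read as log2(RPKM + 1) + 0.0001, a form fitted only on the H460 table, and turned back into RPKM; the design written beforehand had assumed RPKM. Scaled back to reads, 100% of the values lay within 0.01 of a whole number of reads, which gave recovered reads for an alternative analysis. The H820 table held 12 long non-coding RNA genes against 4108 in H460, 92.5% of its genes were protein-coding, and 1909 genes stood at 0 in every library. Gene coordinates are those of hg38.

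Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed. H460 counts were tested with edgeR 4.0.16 (quasi-likelihood fit, robust, TMM scaling, filterByExpr), which left 17426 genes. H820 values were tested with limma 3.58.1 (trend, robust) on log2(RPKM + 0.5) for genes with at least 0.5 RPKM in at least 3 of 12 libraries, which left 13891 genes; this scale understates the fold of low genes. DESeq2 1.42.0 was an alternative for H460. Each line was fitted with its 4 groups of 3 libraries and 5 comparisons: radiation in siCtrl, radiation in siPool, siPool without and after radiation, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. H460 levels are CPM and H820 levels RPKM. R was 4.3.3, python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

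The 23 gene lists covered p53 target, G2 and mitosis, G1/S and DNA replication, replication-dependent histone, homologous recombination and Fanconi, non-homologous end joining, interferon-stimulated, NF-kB and secreted cytokine, apoptosis, NRF2 target, ATF4, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, epithelial-mesenchymal transition, ribosome biogenesis and MYC target, autophagy and lysosome, and mitochondrially encoded genes, small structural RNAs, and alveolar, neuroendocrine, fibroblast and endothelial, and leukocyte markers. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The median, the mean and the test differed in sign only in lists that were not called, among them interferon-stimulated genes in H460 and epithelial-mesenchymal transition genes in both lines. Library scores are medians over a list of log2 values minus the mean of the 12 libraries of the line.

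Named genes were up to 8 per direction past the adjusted p with groups that did not overlap and at least 1 log2 CPM or 2 RPKM, up to 5 for the interaction, and up to 2 called members of a list per direction. CDKN1A, MDM2 and BRCA1 were named in any case; 1 more gene of that rule is not reported here. Up to 3 members of each called list with the lowest p, named as examples, were chosen after values were seen.

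Replicate letters were checked for pairing by correlating library residuals. In H820, where the letter is also the order number of the library names, 18 pairs with the same letter had a mean r of 0.26 (-0.16 to 0.74) and 36 pairs with different letters a mean r of -0.11 (-0.7 to 0.54), so results with the letter as a block are given beside the others. Residuals of a group sum to 0, so these means are not separate evidence of pairing. The 9 same-letter pairs with a siCtrl 8gy library had an r of -0.16 to 0.11 and the other 9 of 0.33 to 0.74. In those other groups, pairs of letter B with letter C had 0.35 to 0.54. Same-letter pairs there had 0.33 to 0.59 in B and C and 0.67 to 0.74 in A. Only letter A thus stood apart, letters B and C were not told apart, and the letter was not shown to pair siCtrl 8gy. In H460 the means were 0.05 and -0.03.

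The pipeline was tested on simulated data made from the real libraries, with 200 changed genes at each fold. At 4-fold it called 30.5% for radiation in H460 siCtrl and 34.5% for siPool without radiation (17426 genes), and 52% and 56% in H820 (15318 genes). At 2-fold it called 0% in each, and at 8-fold 50.5%, 49%, 75.5% and 80.5%. A list of 35 genes raised 2-fold was called in each of the 4 simulations, and 0 of 20 unchanged lists were. Genes were simulated independently of each other, so these runs do not show how list calls fare among correlated genes. In the real H460 libraries the estimated correlation was 0.44 for p53 target genes and 0.73 for G2 and mitosis genes. Every random step used a fixed seed.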

Results

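RNA from H460 and H820, established human non-small cell lung cancer lines, was sequenced after a control or a targeting siRNA treatment, with or without radiation. The siCtrl cells received a scramble siRNA, and the siPool cells received a pool of 3 siRNAs against lnc-RAINY, a long non-coding RNA. Radiation was a dose of 8 Gy (8gy in the labels); NR was read as not irradiated. Each line had 4 groups of 3 libraries, with the replicate letters A, B and C, which made 24 libraries. Totals ran from 16975345 reads (siPool NR A) to 88731527 reads (siCtrl NR B) in H460, and from 14408925 reads (siCtrl NR C) to 48669522 reads (siPool 8gy A) in H820. The design asked how lnc-RAINY affects expression with and without radiation. Levels below are means ± SD over 3 libraries, and changes are log2 values with a standard error (SE). The labels do not say that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

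The target came first: 0 rows of the tables bore the name of lnc-RAINY, so its level was not analysed here and the siRNA labels were not checked by it. The p53 target genes gave another check in H460, a line with wild-type p53, where radiation induces them. Set against the mean of siCtrl NR, the median of the 35 tested p53 target genes lay at 0.80, 0.88 and 1.1 in the siCtrl 8gy libraries A, B and C. The siPool libraries A and B followed their labels, with -0.20 and -0.20 without radiation and 0.92 and 0.98 after it. The library labelled siPool NR C lay at 1.17 and the library labelled siPool 8gy C at -0.34, each opposite to its label. CDKN1A, which encodes the cell cycle inhibitor p21, was at 316.4 CPM (counts scaled to the library total) in the library labelled siPool NR C and at 43.8 CPM in the library labelled siPool 8gy C. Every H460 direction below that uses siPool libraries rests in part on this pair, which was kept as labelled.

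**Figure D1:**
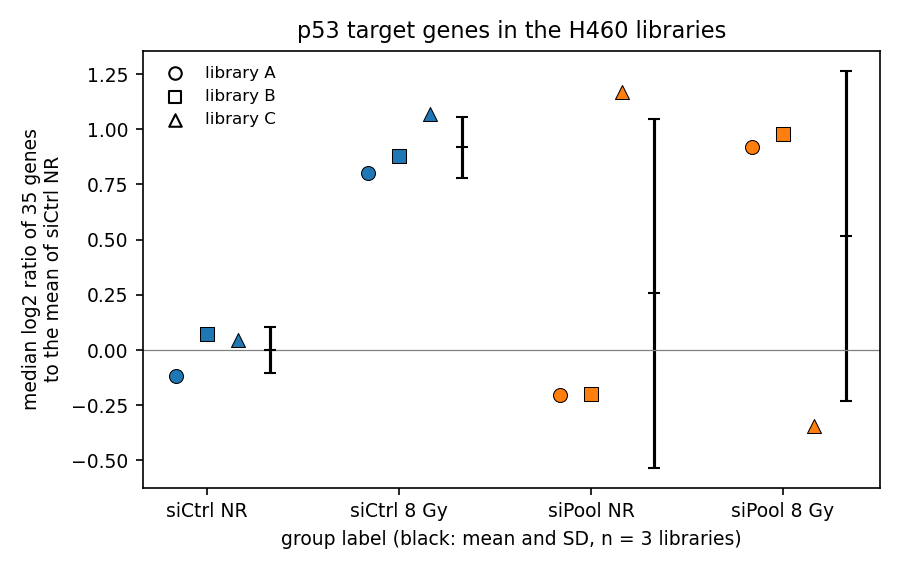
Median log2 difference of 35 p53 target genes from the mean of H460 siCtrl NR (vertical axis), 1 point per library by group, with the marker shape giving the replicate letter and black bars the group mean and SD. The library labelled siPool NR C sits at 1.17 and the library labelled siPool 8gy C at -0.34.

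Radiation in H460 siCtrl cells was followed by higher p53 target genes and lower histone genes. Cell cycle and homologous recombination genes had lower medians, but the groups overlapped and single libraries ended those calls. Of 35 tested p53 target genes 33 had a positive change, with a median of 0.90, and camera gave an adjusted p of 4.59e-12 (adjusted p = 0.431 with an estimated correlation). CDKN1A stood at 67.8 ± 16.4 CPM without and 313.8 ± 72.7 CPM after radiation, a change of 2.21 (SE 0.87). MDM2, whose product marks p53 for degradation, stood at 265.1 ± 59.7 and 828.5 ± 263 CPM, a change of 1.64 (SE 0.495). TIGAR, a regulator of glycolysis, changed by 1.53 (SE 0.467) and RRM2B, a ribonucleotide reductase subunit, by 1.36 (SE 0.425). None of these 4 genes passed over all genes in edgeR (adjusted p = 1 for each).

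Replication-dependent histone genes lay lower in H460 siCtrl after radiation, with 3 of 37 members positive and a median of -1.46 (camera adjusted p = 2.09e-07; adjusted p = 0.591 with an estimated correlation). H2AC20 stood at 114.6 ± 34.8 and 53.6 ± 11.8 CPM (-1.10, SE 0.411), and H2AC16 changed by -3.06 (SE 1.0). The G2 and mitosis genes had 3 of 35 members positive and a median of -0.99 (adjusted p = 0.000497; adjusted p = 0.851 with an estimated correlation); KIF11, a spindle motor, was at 27.9 ± 20.3 and 10.9 ± 6.08 CPM. The G1/S and DNA replication genes had a median of -0.48 with 7 of 38 positive (adjusted p = 0.0453; adjusted p = 0.851 with an estimated correlation). Among them CDT1, which licenses replication origins, was at 31.4 ± 6.0 and 12.0 ± 3.05 CPM (-1.38, SE 0.399). Homologous recombination and Fanconi genes had a median of -0.43 with 8 of 38 positive (adjusted p = 0.0127; adjusted p = 0.847 with an estimated correlation). BRCA1 changed by -0.90 (SE 0.753) and RAD54L, both of recombination repair, by -1.34 (SE 0.634). The library siCtrl 8gy B stood apart on the third principal component (-184.1) and was lowest of the 12 on the mitosis genes, at -2.20 from the mean of the line. On the mitosis genes siCtrl NR A scored -0.95, below siCtrl 8gy A (-0.50) and siCtrl 8gy C (-0.23). On the G1/S genes siCtrl NR A scored -0.76, below siCtrl 8gy A (-0.28) and siCtrl 8gy C (0.10). Letter A thus showed no lowering of either list.

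Higher groups in the same H460 comparison were the unfolded protein response genes (23 of 25 positive, median 0.31, adjusted p = 5.27e-05), cholesterol synthesis genes (20 of 24, 0.55, adjusted p = 3.1e-05) and autophagy and lysosome genes (28 of 37, 0.40, adjusted p = 0.000113). Each had an adjusted p = 0.431 with an estimated correlation. The chaperone CALR stood at 660.2 ± 179 and 1447 ± 492 CPM (1.1, SE 0.372), HMGCS1, an enzyme of the mevalonate pathway, changed by 1.24 (SE 0.463), and the lysosomal sialidase NEU1 stood at 82.0 ± 8.76 and 165.4 ± 15.8 CPM (1.0, SE 0.349). NF-kB and secreted cytokine genes had 18 of 26 positive and a median of 0.60 (adjusted p = 0.0107; adjusted p = 0.558 with an estimated correlation), with CXCL8, a neutrophil chemokine, at 122 ± 49.7 and 459.4 ± 534 CPM. Adjusted over the list alone, 1 gene passed in all lists, the mucin gene MUC1 among the alveolar markers (-1.25, SE 0.389, adjusted p = 0.0374), a list that was not called.

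edgeR called 0 of 17426 genes for radiation in H460 siCtrl, with 653 at an unadjusted p under 0.05 where chance gives 871. DESeq2 called 25, and limma-voom with sample quality weights 3. Single libraries ended list calls as follows. Without siCtrl 8gy B the adjusted p was 0.18 for homologous recombination, 0.231 for NF-kB, 0.31 for mitosis (median -0.53) and 0.64 for G1/S genes (median -0.16). Without letter B the medians were -0.07 for mitosis and -0.01 for G1/S genes, so almost no lowering of either was left. Without siCtrl NR B it was 0.083 for mitosis, 0.181 for G1/S and 0.212 for homologous recombination genes. Without siCtrl 8gy A it was 0.0963 for homologous recombination and 0.119 for G1/S genes, without siCtrl NR C 0.484 for G1/S genes, and without siCtrl NR A 0.0627 for unfolded protein response genes. The p53 target, histone, cholesterol and autophagy calls held without each single library, with medians of 0.36 for cholesterol genes without siCtrl NR A and 0.21 for autophagy genes without siCtrl 8gy B. Without letter B the autophagy call was lost (median 0.19, adjusted p = 0.061).

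The siRNA pool without radiation in H460 went with higher cell cycle, ribosome biogenesis, mitochondrially encoded and p53 target genes. None of these calls held without the library labelled siPool NR C, on which the p53 target, mitochondrial and ribosome biogenesis directions rest. Mitochondrially encoded genes had 15 of 15 members positive and a median of 1.66 (camera adjusted p = 0.000104), G2 and mitosis genes 34 of 35 and 0.78 (adjusted p = 0.00139), and G1/S genes 35 of 38 and 0.54 (adjusted p = 0.028). Ribosome biogenesis and MYC target genes had 29 of 32 positive and a median of 0.26 (adjusted p = 0.000253), and p53 target genes 26 of 35 and 0.42 (adjusted p = 0.0337). Each of these 5 had an adjusted p = 0.921 with an estimated correlation. ND5, a subunit of respiratory complex I, stood at 1525 ± 449 CPM in siCtrl and 4833 ± 3310 CPM in siPool. Adjusted over the list alone, ND5 (1.66, SE 0.513) and ND6 (1.68, SE 0.509) passed, each with an edgeR adjusted p of 0.0353, and over all genes edgeR called 0. POLA1, of DNA polymerase alpha, was at 46.1 ± 15.1 and 92.1 ± 16.6 CPM (1.00, SE 0.416), DKC1, which modifies ribosomal RNA, at 73.7 ± 7.32 and 125.5 ± 13.9 CPM (0.77, SE 0.332), and KITLG, a growth factor of the p53 list, at 9.38 ± 3.33 and 28.8 ± 10.7 CPM (1.61, SE 0.456).

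The libraries of this group were uneven. The library labelled siPool NR C had the highest score of the 12 for mitochondrially encoded genes (2.51 from the mean of the line, others -1.23 to 0.59) and for small structural RNAs (1.75, others -0.98 to 0.36), and siPool NR A lay apart on the first principal component (311). In siPool NR A 44.9% of genes stood at 0, the highest share of the 12. It had 190 genes with 11 to 50 reads, and siPool 8gy A had 297, against 1246 to 1992 in the other H460 libraries. The limma-voom quality weight of siPool NR A was 0.223, the lowest of the 12. Without the library labelled siPool NR C none of the 5 calls held: the adjusted p was 0.137 for mitosis, 0.137 for ribosome biogenesis (median -0.01), 0.349 for G1/S, 0.349 for mitochondrial (median -0.41) and 0.916 for p53 target genes (median -0.24). Without siPool NR B the adjusted p was 0.515 for mitosis and 0.703 for G1/S genes. Without siCtrl NR A it was 0.182 for p53 target, 0.267 for mitosis and 0.452 for G1/S genes, and without siCtrl NR B 0.0848 for p53 target genes. More lists were called without siPool NR A (10) and without siCtrl NR C (9) than the 5 with all libraries. CDKN1A stood at 138.8 ± 154 CPM (1.0, SE 0.841), MDM2 changed by 0.55 (SE 0.484) and BRCA1 by 0.79 (SE 0.749). edgeR called 0 genes, with 712 at an unadjusted p under 0.05. DESeq2 called 11, limma-voom with quality weights 50, and edgeR with no filter 5. Without siPool NR A edgeR called 3: MYPN, a muscle sarcomere gene (3.15, SE 0.497), was higher, and NT5E, an ecto-nucleotidase (-2.57, SE 0.42), and PAEP, a secreted lipocalin (-3.21, SE 0.478), were lower.

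After radiation in H460, siPool went with higher cell cycle, histone and homologous recombination genes and lower p53 target, NF-kB, ATF4 and autophagy genes than siCtrl, where the p53 target, histone and autophagy calls needed the library labelled siPool 8gy C and the ATF4 and NF-kB calls rested mainly on siCtrl 8gy B. The G2 and mitosis genes had 35 of 35 positive and a median of 1.73 (camera adjusted p = 1.67e-11), G1/S genes 36 of 38 and 1.20 (adjusted p = 3.41e-07), histone genes 37 of 37 and 1.34 (adjusted p = 4.09e-05), homologous recombination and Fanconi genes 36 of 38 and 0.52 (adjusted p = 5.09e-07), and ribosome biogenesis genes 29 of 32 and 0.44 (adjusted p = 0.00024). The lower lists were p53 target genes (11 of 35 positive, -0.28, adjusted p = 0.0202), NF-kB genes (7 of 26, -0.47, adjusted p = 0.0112), ATF4 genes (5 of 27, -0.39, adjusted p = 0.0441) and autophagy and lysosome genes (6 of 37, -0.32, adjusted p = 0.00024). Each of these 9 had an adjusted p = 0.637 with an estimated correlation. BLM, a helicase of recombination, stood at 3.58 ± 1.1 CPM in siCtrl and 19.9 ± 3.59 in siPool (2.47, SE 0.559); adjusted over the list alone it passed as 1 gene of 38 (edgeR adjusted p = 0.0121); over all genes edgeR called 0, while DESeq2 called BLM. H2AC16 was at 1.2 ± 1.0 and 14.1 ± 9.39 CPM (3.59, SE 1.0), and DLGAP5, a spindle protein, at 4.06 ± 3.03 and 23.2 ± 24 CPM (2.51, SE 0.844). CCNG1, a cyclin of the p53 response, was at 152.9 ± 57 and 70.7 ± 12.2 CPM (-1.11, SE 0.36), and PTGS2, the inducible cyclooxygenase, changed by -1.95 (SE 0.863). CDKN1A was at 199.6 ± 190 CPM in siPool (-0.65, SE 0.835), MDM2 changed by -0.43 (SE 0.484) and BRCA1 by 1.59 (SE 0.764).

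edgeR called 0 genes in this comparison, with 641 at an unadjusted p under 0.05, and DESeq2 called 34. Without the library labelled siPool 8gy C the adjusted p was 0.0744 for ATF4 and for ribosome biogenesis, 0.187 for NF-kB, 0.299 for autophagy, 0.51 for histone and 0.797 for p53 target genes, while the mitosis, G1/S and homologous recombination calls held. Medians without it were 1.0 for mitosis, 0.67 for G1/S, 0.32 for homologous recombination, 0.32 for histone and -0.04 for p53 target genes. Its mitosis score was 1.91 from the mean of the line, against -2.20 for siCtrl 8gy B. The library siPool 8gy A lay apart on the second principal component (177.4). It had few genes with 11 to 50 reads (297) and a limma-voom quality weight of 0.415. Without siCtrl 8gy B the adjusted p was 0.307 for NF-kB (median -0.18) and 0.425 for ATF4 genes (median -0.01), and without letter B the ATF4 median was 0.11, so the ATF4 direction was not kept. ATF4 genes also had 0.158 without siPool 8gy A and 0.161 without siPool 8gy B, and p53 target genes 0.349 without siCtrl 8gy C.

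Radiation in H460 siPool cells gave no called list with the libraries as labelled. The p53 target genes had 27 of 35 positive and a median of 0.25 (camera adjusted p = 0.279), and the lowest adjusted p of any list was 0.077, shared by histone genes (median -0.37), mitochondrially encoded genes (-0.98) and small structural RNAs (-1.12). CDKN1A changed by 0.52 (SE 0.834), MDM2 by 0.66 (SE 0.485) and BRCA1 by -0.10 (SE 0.745). edgeR called 0 genes, with 302 at an unadjusted p under 0.05, and DESeq2 called 22. The libraries labelled siPool C were picked out by their p53 target scores, so p53 results without them are not used here. Without 1 library the number of lists called was 6 without siPool NR A, 3 without siPool 8gy A, 2 without siPool NR B, 3 without siPool 8gy B, 3 without the library labelled siPool NR C and 5 without the library labelled siPool 8gy C.

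The interaction in H460, the radiation effect in siPool minus that in siCtrl, was called for 6 lists, and each direction uses the pair labelled siPool C. It was negative for p53 target genes (4 of 35 positive, median -0.63, adjusted p = 0.000543), unfolded protein response genes (8 of 25, -0.26, adjusted p = 0.044), cholesterol synthesis genes (6 of 24, -0.45, adjusted p = 0.0435), autophagy genes (14 of 37, -0.19, adjusted p = 0.044) and mitochondrially encoded genes (0 of 15, -1.01, adjusted p = 0.0435). It was positive for G2 and mitosis genes (34 of 35, 0.97, adjusted p = 0.044). Each of these 6 had an adjusted p = 0.862 with an estimated correlation. CDKN1A had an interaction of -1.69 (SE 1.19), MDM2 of -0.98 (SE 0.684), TIGAR of -1.44 (SE 0.649), BRCA1 of 0.80 (SE 1.1) and FOXM1, a mitotic transcription factor, of 1.27 (SE 1.1). edgeR called 0 genes, with 318 at an unadjusted p under 0.05, and DESeq2 called 21.

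Leaving out single libraries ended most of these H460 interaction calls. The p53 call was lost without the library labelled siPool NR C (adjusted p = 0.178, median 0.16) and without the library labelled siPool 8gy C (adjusted p = 0.513). All 6 calls were lost without siPool NR C (adjusted p 0.14 to 0.914, mitochondrial median 0.70) and without siPool 8gy C (0.225 to 0.806). Without siCtrl NR A 4 were lost (0.0712 to 0.585), without siCtrl 8gy C 4 (0.0614 to 0.346), without siCtrl 8gy A 3 (0.0592 to 0.0788) and without siCtrl 8gy B 3 (0.136 to 0.59). The losses were 2 each without siPool NR A (0.162 to 0.642), siCtrl NR B (0.167 to 0.277), siPool NR B (0.0893 to 0.164), siPool 8gy B (0.0557 to 0.0771) and siCtrl NR C (0.0559 to 0.12). Without siPool 8gy A 10 lists were called.

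In H820 siCtrl cells a few lists lay slightly higher or lower after radiation, and none of these calls held with an estimated correlation. Mitochondrially encoded genes lay lower, with 1 of 15 positive and a median of -0.45 (camera adjusted p = 0.00412; adjusted p = 0.449 with an estimated correlation), as did hypoxia and glycolysis genes (3 of 29, -0.27, adjusted p = 0.00412; adjusted p = 0.449 with an estimated correlation). Alveolar and lung lineage markers had 3 of 13 positive and a median of -0.30 (adjusted p = 0.0295; adjusted p = 0.436 with an estimated correlation), with CEACAM6, an adhesion protein, at 18.3 ± 10.1 and 5.18 ± 2.13 RPKM (-1.59, SE 0.659). NRF2 target genes had 8 of 29 positive and a median of -0.13 (adjusted p = 0.047; adjusted p = 0.311 with an estimated correlation), and ribosome biogenesis genes 11 of 32 and -0.09 (adjusted p = 0.0329; adjusted p = 0.607 with an estimated correlation). Interferon-stimulated genes lay higher, with 25 of 38 positive and a median of 0.21 (adjusted p = 0.044; adjusted p = 0.449 with an estimated correlation), and IFIT3, which restrains viral RNA translation, at 5.90 ± 1.79 and 9.22 ± 0.895 RPKM (0.64, SE 0.291). Apoptosis regulators had 18 of 27 positive and a median of 0.15 (adjusted p = 0.047; adjusted p = 0.311 with an estimated correlation). With the letter as a block the apoptosis call ended (adjusted p = 0.0564) and NF-kB genes were called (adjusted p = 0.0262; adjusted p = 0.335 with the block and an estimated correlation). The p53 target genes had 20 of 33 positive and a median of 0.09 (adjusted p = 0.506); CDKN1A stood at 20.6 ± 3.5 and 30.2 ± 16.6 RPKM (0.43, SE 0.356), MDM2 changed by 0.28 (SE 0.259) and BRCA1 by 0.08 (SE 0.255).

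limma called 0 of 13891 genes for radiation in H820 siCtrl, with 408 at an unadjusted p under 0.05 where chance gives 695; edgeR on reads recovered from the values also called 0, and limma with no filter called 1, the keratin gene KRT83. On mitochondrially encoded genes siCtrl NR A scored 1.37 and siCtrl 8gy A -1.34 from the mean of the line, outside the other 10 libraries. The scores in siCtrl NR and siCtrl 8gy were -0.23 and -0.28 in letter B, and -0.74 and 0.20, a rise, in letter C. Without siCtrl 8gy A all 7 list calls ended (adjusted p 0.0569 to 0.809), and without siCtrl 8gy C all but the mitochondrial one did (0.0626 to 0.256). Without siCtrl NR A the NRF2, apoptosis, alveolar and mitochondrial calls ended (0.136 to 0.925) and the mitochondrial median turned to 0.17, against 0.40 without letter A, and without siCtrl NR B the hypoxia, interferon and ribosome biogenesis calls (0.104 to 0.214). Without siCtrl 8gy B the mitochondrial, interferon, apoptosis and NRF2 calls ended (0.0536 to 0.184), and without siCtrl NR C the apoptosis, NRF2, interferon and ribosome biogenesis calls (0.0856 to 0.386).

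The siRNA pool without radiation in H820 lowered 7 genes and raised 0 at a limma adjusted p under 0.05. AKR1C1, an aldo-keto reductase, fell from 19.1 ± 3.87 to 3.03 ± 0.675 RPKM (-2.47, SE 0.266, adjusted p = 0.00499). NDRG1, a stress-responsive gene induced by hypoxia, fell from 65.0 ± 15.9 to 14.7 ± 1.18 RPKM (-2.08, SE 0.205, adjusted p = 0.00367). PLOD2, which hydroxylates lysines of collagen, fell from 188.8 ± 58 to 44.7 ± 7.35 RPKM (-2.03, SE 0.274, adjusted p = 0.0325), and AREG, the EGFR ligand amphiregulin, from 401.6 ± 154 to 115.5 ± 3.61 RPKM (-1.73, SE 0.244, adjusted p = 0.0325). B3GNT5, a glycosyltransferase of glycolipids, fell from 21.5 ± 6.1 to 6.53 ± 0.729 RPKM (-1.61, SE 0.24, adjusted p = 0.0414), ATP2B4, a calcium pump of the plasma membrane, from 62.8 ± 9.29 to 24.9 ± 3.03 RPKM (-1.32, SE 0.185, adjusted p = 0.0325), and LYN, a Src family kinase, from 29.3 ± 1.68 to 12.2 ± 1.22 RPKM (-1.24, SE 0.181, adjusted p = 0.0376). In each of the 7 every siPool library lay below every siCtrl library, a separation that chance gives, in either direction, for 10% of genes. On hg38 the genes span 10:4963415-4983283 (AKR1C1), 8:133237175-133297252 (NDRG1), 3:146069440-146161184 (PLOD2), 4:74445136-74455005 (AREG), 3:183253253-183273385 (B3GNT5), 1:203626832-203744081 (ATP2B4) and 8:55879835-56014169 (LYN).

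**Figure D2:**
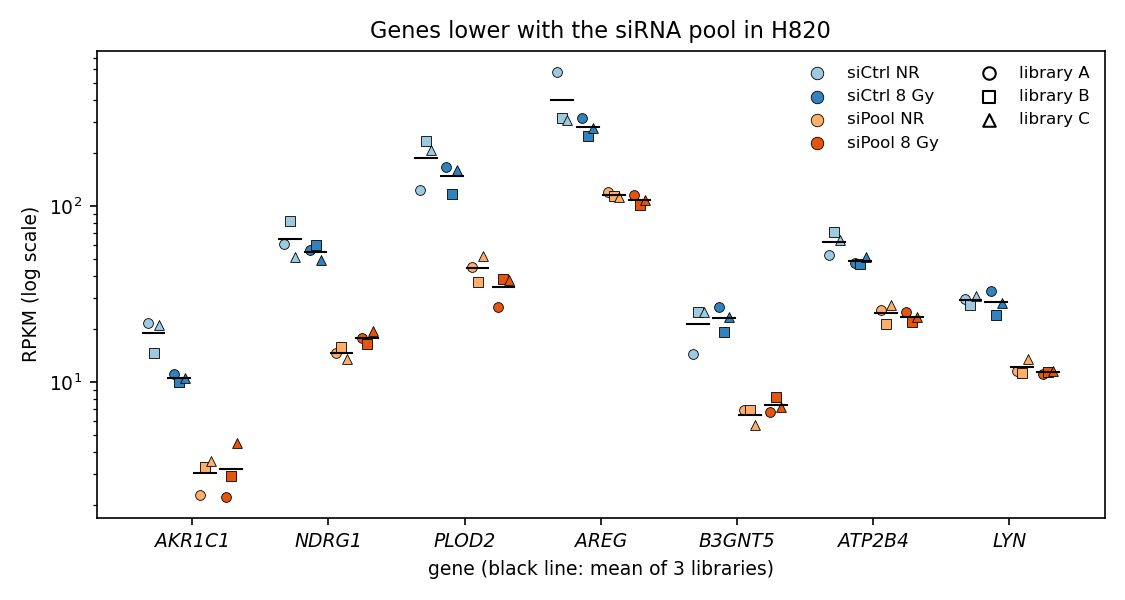
RPKM (log axis) of the 7 genes that fell with siPool without radiation in H820, 1 point per library in the siCtrl and siPool groups with and without radiation, with marker shapes for the replicate letters and black lines for group means. For AKR1C1 the mean was 19.1 RPKM in siCtrl NR and 3.03 in siPool NR.

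With the letter as a block, limma called 13 genes, all lower. The added genes were SERPINA3, a secreted protease inhibitor (175.6 ± 201 and 17.9 ± 10.3 RPKM, -2.76, blocked SE 0.371, blocked adjusted p = 0.03 against 0.345 without it), CHI3L2, a chitinase-like protein (-2.06, blocked adjusted p = 0.03), AGR2, a disulfide isomerase of secretory cells (27 ± 7.61 and 6.31 ± 1.88 RPKM, -2.02, blocked adjusted p = 0.03), GET1, a receptor for tail-anchored proteins (-1.45, blocked adjusted p = 0.03), STARD3NL, a late endosome protein (-1.44, blocked adjusted p = 0.03) and ZG16B, a secreted lectin (-1.88, blocked adjusted p = 0.0344). GET1, STARD3NL and ZG16B were named after their values were seen. edgeR on recovered reads called 7 genes, and 20 with the block. With only the 6 compared libraries in the model limma called 0, with 1119 genes at an unadjusted p under 0.05. Leaving out 1 library left NDRG1 called each time: 9 genes passed without siCtrl NR A, 2 without siPool NR A, siCtrl NR B, siPool NR B or siPool NR C (AKR1C1 and NDRG1 in each), and 1 without siCtrl NR C. Calls were also lost without a whole letter. Of the 9 fits with a library or a letter left out, NDRG1 passed in 7 and AKR1C1 in 6. PLOD2, AREG, B3GNT5 and ATP2B4 passed in 2 each and LYN in 0.

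Cell cycle and homologous recombination genes lay higher in H820 siPool without radiation. The G1/S and DNA replication genes had 38 of 38 positive and a median of 0.64 (camera adjusted p = 5.6e-17), homologous recombination and Fanconi genes 37 of 38 and 0.50 (adjusted p = 2.92e-11), and G2 and mitosis genes 31 of 35 and 0.45 (adjusted p = 1.9e-08). Each had an adjusted p = 0.131 with an estimated correlation and 0.0128 by fry. The calls held with a library or letter left out, where the lowest medians were 0.402, 0.333 and 0.327 in this order. On G1/S genes siCtrl NR A scored -0.73, against -0.12 and -0.2 in siCtrl NR B and C. Adjusted over the list alone, 16 G1/S genes and 7 recombination genes were higher, against 0 of either over all genes. MCM3, of the replicative helicase, stood at 23.6 ± 2.87 and 44.8 ± 5.27 RPKM (0.91, SE 0.186), FEN1, a flap endonuclease, at 12.1 ± 3.29 and 25.9 ± 2.06 RPKM (1.1, SE 0.26), RAD54L at 7.14 ± 0.56 and 14.4 ± 3.3 RPKM (0.94, SE 0.215) and FOXM1 at 29 ± 1.69 and 55.1 ± 11.7 RPKM (0.90, SE 0.249). BRCA1 changed by 0.59 (SE 0.255), CDKN1A by -0.60 (SE 0.356) and MDM2 by 0.12 (SE 0.259). Ribosome biogenesis and MYC target genes had 32 of 32 positive and a median of 0.50 (adjusted p = 2.27e-07; adjusted p = 0.287 with an estimated correlation), and of 0.295 without siCtrl NR A.

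Lower lists in this H820 comparison were NRF2 target, hypoxia, alveolar, cholesterol and unfolded protein response genes. NRF2 target genes had 8 of 29 positive and a median of -0.32 (adjusted p = 6.5e-06), and theirs was the only list call of the 10 comparisons that held with an estimated correlation (adjusted p = 0.0132). Letter A showed no lowering of the NRF2 list, with scores of -0.09 in siCtrl NR and 0.01 in siPool NR. Letters B and C scored 0.21 and 0.26 in siCtrl NR and -0.24 and -0.18 in siPool NR. AKR1C1 was the 1 member past the test over all genes and adjusted over the list alone; TXNRD1, thioredoxin reductase, stood at 274.4 ± 69.4 and 157.7 ± 23.4 RPKM (-0.77, SE 0.264). Hypoxia and glycolysis genes had 2 of 29 positive and a median of -0.34 (adjusted p = 1.39e-07; adjusted p = 0.199 with an estimated correlation). Of them 4 passed adjusted over the list alone and 1, NDRG1, over all genes; EGLN3, a prolyl hydroxylase of HIF, stood at 25 ± 10.9 and 7.83 ± 0.83 RPKM (-1.53, SE 0.293). Alveolar markers had 3 of 13 positive and a median of -0.44 (adjusted p = 0.000426; adjusted p = 0.172 with an estimated correlation), and 1 passed adjusted over the list alone, the surfactant lipid transporter ABCA3 (18.2 ± 0.515 and 8.66 ± 1.84 RPKM, -1.04, SE 0.249). Cholesterol synthesis genes (6 of 25, -0.18) and unfolded protein response genes (6 of 25, -0.11) had adjusted p of 0.0216 and 0.0373, each with an adjusted p = 0.289 with an estimated correlation. PDIA3, a disulfide isomerase, was the 1 unfolded protein response gene that passed adjusted over the list alone (-0.90, SE 0.213). The unfolded protein response call ended without siCtrl NR A (adjusted p = 0.106), siCtrl NR B (0.0628) or siPool NR B (0.184), and the cholesterol call without siCtrl NR A (0.182) or siPool NR B (0.184). The hypoxia, alveolar and NRF2 calls held without each library, but medians moved. That of hypoxia genes was -0.635 without siCtrl NR A and -0.14 without siCtrl NR B, and that of NRF2 target genes -0.49 without siCtrl NR B. The alveolar median was -0.25 without siCtrl NR A, -0.78 without siPool NR A, -0.21 without siPool NR B and -0.81 without siCtrl NR C. With the block, NF-kB genes (adjusted p = 0.0373) and leukocyte markers (adjusted p = 0.039) were also called lower, and neither held with an estimated correlation (adjusted p = 0.174 and 0.232).

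After radiation in H820, siPool lowered 2 genes against siCtrl and raised 0. PLOD2 fell from 148 ± 26.8 to 34.6 ± 6.73 RPKM (-2.09, SE 0.274, limma adjusted p = 0.041) and NDRG1 from 55.1 ± 5.38 to 17.9 ± 1.51 RPKM (-1.59, SE 0.205, adjusted p = 0.041), each with every siPool library below every siCtrl library. With the letter as a block 3 genes were called, with GET1 (21:39380326-39428528 on hg38) added at 9.27 ± 1.46 and 2.37 ± 0.335 RPKM (-1.76, blocked adjusted p = 0.0261 against 0.0771 without it). Same-letter siCtrl 8gy libraries were not shown to pair, so blocked values that use that group are less certain. In the other groups only letter A stood apart from letters B and C. AKR1C1 stood at 10.6 ± 0.604 and 3.23 ± 1.18 RPKM (-1.62, SE 0.266, adjusted p = 0.0865). edgeR on recovered reads called 5 genes, and 12 with the block; with only the 6 compared libraries limma called 0. Without siCtrl 8gy A, siPool 8gy A, siPool 8gy B, siCtrl 8gy C or siPool 8gy C limma called 0 genes, and without siCtrl 8gy B it called 166, of which 2 were shared with the count of 2. Both genes were also the overlap with the 7 genes lower without radiation, where independent lists would share 0.00101. The lists are not independent, since 1 fit gave each gene the same SE in both comparisons. Genes with a small SE can pass in both more often, so that value is no measure of a shared effect. Across the 13891 genes the siPool effects with and without radiation had a Pearson r of 0.59 and a Spearman rho of 0.56, a description across genes, which are not independent replicates.

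The list directions in H820 siPool after radiation followed part of those without it: G2 and mitosis genes (25 of 35 positive, median 0.19, adjusted p = 0.0688) and alveolar markers (4 of 13, -0.12, adjusted p = 0.1) were no longer called. Called lists had medians of 0.53 for G1/S genes (36 of 38 positive, camera adjusted p = 1.44e-10), 0.33 for homologous recombination genes (37 of 38, adjusted p = 6.4e-07), -0.21 for NRF2 target genes (11 of 29, adjusted p = 0.00135) and -0.26 for unfolded protein response genes (3 of 25, adjusted p = 2.42e-05). With an estimated correlation the adjusted p = 0.0767 for NRF2 target genes and 0.184 for the other 3. Letter A again showed no lowering of NRF2 target genes, with scores of -0.02 in siCtrl 8gy and 0.06 in siPool 8gy. Adjusted over the list alone, 2 NRF2 target genes passed, AKR1C1 and AKR1C3 (-1.26, SE 0.284), and 0 over all genes; PDIA3 stood at 73.7 ± 14.9 and 30 ± 2.8 RPKM (-1.27, SE 0.213) and was the 1 unfolded protein response gene to pass that way. Ribosome biogenesis genes had 31 of 32 positive and a median of 0.56 (adjusted p = 3.44e-10), and cholesterol synthesis genes 6 of 25 and -0.20 (adjusted p = 0.00135), each with an adjusted p = 0.224 with an estimated correlation. Hypoxia genes had 9 of 29 positive and a median of -0.17 (adjusted p = 0.00534; adjusted p = 0.503 with an estimated correlation), with 2 lower adjusted over the list alone and 1, NDRG1, over all genes. Autophagy genes (13 of 36, -0.09, adjusted p = 0.0348) and apoptosis regulators (12 of 27, -0.05, adjusted p = 0.0445) had an adjusted p = 0.184 with an estimated correlation, and the block ended both calls (adjusted p = 0.0512 and 0.0666). Adjusted over the list alone, BCL2A1, an inhibitor of apoptosis, was lower (26.1 ± 8.59 and 10.2 ± 2.05 RPKM, -1.27, SE 0.3). Mitochondrially encoded genes had 13 of 15 positive and a median of 0.86 (adjusted p = 0.0181; adjusted p = 0.569 with an estimated correlation), beside the score of -1.34 in siCtrl 8gy A.

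Single libraries ended some of these calls. Without siCtrl 8gy B the adjusted p was 0.0565 for NRF2, 0.219 for mitochondrial, 0.271 for apoptosis and autophagy and 0.707 for hypoxia genes (median 0.08). Without siPool 8gy B it was 0.0659 for apoptosis and mitochondrial genes and 0.152 for autophagy genes, without siPool 8gy A 0.141 for apoptosis genes, and without siCtrl 8gy A 0.25 and without siPool 8gy C 0.171 for mitochondrial genes. Without letter B the adjusted p was 0.191 for homologous recombination and for NRF2 target genes, and without letter C 0.0589 for cholesterol genes. The NRF2 median was -0.08 without siCtrl 8gy B or siPool 8gy B, and the cholesterol and hypoxia medians were -0.03 without siPool 8gy B. limma found 920 genes at an unadjusted p under 0.05 in the comparison, where chance gives 695. CDKN1A changed by -0.09, MDM2 by -0.15 and BRCA1 by 0.45, none past the test. The p53 target genes had a median of -0.03 (adjusted p = 0.622).

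Radiation in H820 siPool cells was followed by higher NF-kB and interferon-stimulated genes and slightly lower homologous recombination, mitosis, unfolded protein response and cholesterol genes. NF-kB genes had 26 of 33 positive and a median of 0.28 (camera adjusted p = 0.00166; adjusted p = 0.124 with an estimated correlation), with the chemokine CCL20 at 2.15 ± 0.872 and 4.32 ± 1.64 RPKM (0.86, SE 0.462). Interferon-stimulated genes had 24 of 38 positive and a median of 0.11 (adjusted p = 0.0134; adjusted p = 0.419 with an estimated correlation), with IFI6 at 36.4 ± 11.9 and 70.9 ± 13.5 RPKM (0.98, SE 0.343). Homologous recombination genes had 5 of 38 positive (-0.17, adjusted p = 0.000213), mitosis genes 7 of 35 (-0.11, adjusted p = 0.000367), unfolded protein response genes 6 of 25 (-0.16, adjusted p = 0.00356) and cholesterol synthesis genes 6 of 25 (-0.17, adjusted p = 0.00356), each with an adjusted p = 0.357 with an estimated correlation. HSPA5, the endoplasmic reticulum chaperone BiP, stood at 176.2 ± 26 and 135.1 ± 10.7 RPKM (-0.38, SE 0.194). CDKN1A stood at 13.5 ± 2.93 and 27.1 ± 10.1 RPKM (0.93, SE 0.356), MDM2 changed by 0.01 and BRCA1 by -0.06, and p53 target genes had a median of 0.04 (adjusted p = 0.329). limma called 0 genes, with 74 at an unadjusted p under 0.05, and edgeR on recovered reads called 0. Without siPool NR A the adjusted p was 0.0584 for mitosis, 0.127 for unfolded protein response and 0.589 for cholesterol genes, and without siPool 8gy A 0.0591 for NF-kB and 0.0807 for homologous recombination genes. Without siPool 8gy B it was 0.153 for unfolded protein response and 0.225 for cholesterol genes, and without siPool NR C 0.0777 for NF-kB and 0.999 for interferon genes (median -0.01). Without siPool 8gy C it was 0.0797 for unfolded protein response, 0.108 for mitosis, 0.289 for cholesterol and 0.517 for interferon genes.

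The interaction in H820 was called for 6 lists. It was negative for G2 and mitosis genes (1 of 35 positive, median -0.22, adjusted p = 1.83e-05), G1/S genes (11 of 38, -0.20, adjusted p = 0.0213) and unfolded protein response genes (5 of 25, -0.19, adjusted p = 0.0422), and positive for mitochondrially encoded genes (15 of 15, 1.0, adjusted p = 1.83e-05), hypoxia genes (26 of 29, 0.23, adjusted p = 0.00492) and alveolar markers (10 of 13, 0.36, adjusted p = 0.0449). With an estimated correlation the adjusted p = 0.621 for G1/S genes and 0.532 for the other 5, and the block ended the alveolar call (adjusted p = 0.0879). BIRC5, which encodes survivin, had an interaction of -0.84 (SE 0.367), NDRG1 of 0.49 (SE 0.29), CDKN1A of 0.51, MDM2 of -0.27, BRCA1 of -0.14 and ND4, of complex I, of 1.40 (SE 0.887). limma called 0 genes, with 89 at an unadjusted p under 0.05; edgeR on recovered reads called 0, and limma with no filter 1, KRT83. The mitosis call held without each single library, and was lost without letter A (median -0.05, adjusted p = 0.563). The mitochondrial median was 0.43 without siCtrl NR A, where the call was lost (adjusted p = 0.242), 0.57 without siCtrl 8gy A, and 0.12 without letter A (adjusted p = 0.687).

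The other H820 interaction calls were lost as follows. Without siCtrl NR A the unfolded protein response, alveolar and G1/S calls were lost too (adjusted p 0.0676 to 0.909 over all 4). The hypoxia call was lost, each time with 2 others, without siCtrl 8gy A (0.279 to 0.42), siPool NR A (0.0892 to 0.234) and siCtrl NR B (0.0881 to 0.181). For alveolar markers the adjusted p was 0.734 without siPool 8gy A, 0.291 without siPool NR B and 0.0867 without siCtrl 8gy C. For G1/S genes it was 0.379 without siCtrl 8gy B, 0.0578 without siPool NR B, 0.159 without siPool 8gy B and 0.286 without siPool 8gy C. Over the fits with a library or letter left out, the lowest alveolar median was -0.04 and the highest G1/S median 0.02. Neither direction was thus kept in every fit. For unfolded protein response genes the adjusted p was 0.161 without siPool 8gy B, 0.155 without siCtrl NR C, 0.203 without siCtrl 8gy C, 0.134 without siPool NR C and 0.104 without siPool 8gy C.

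**Figure D3:**
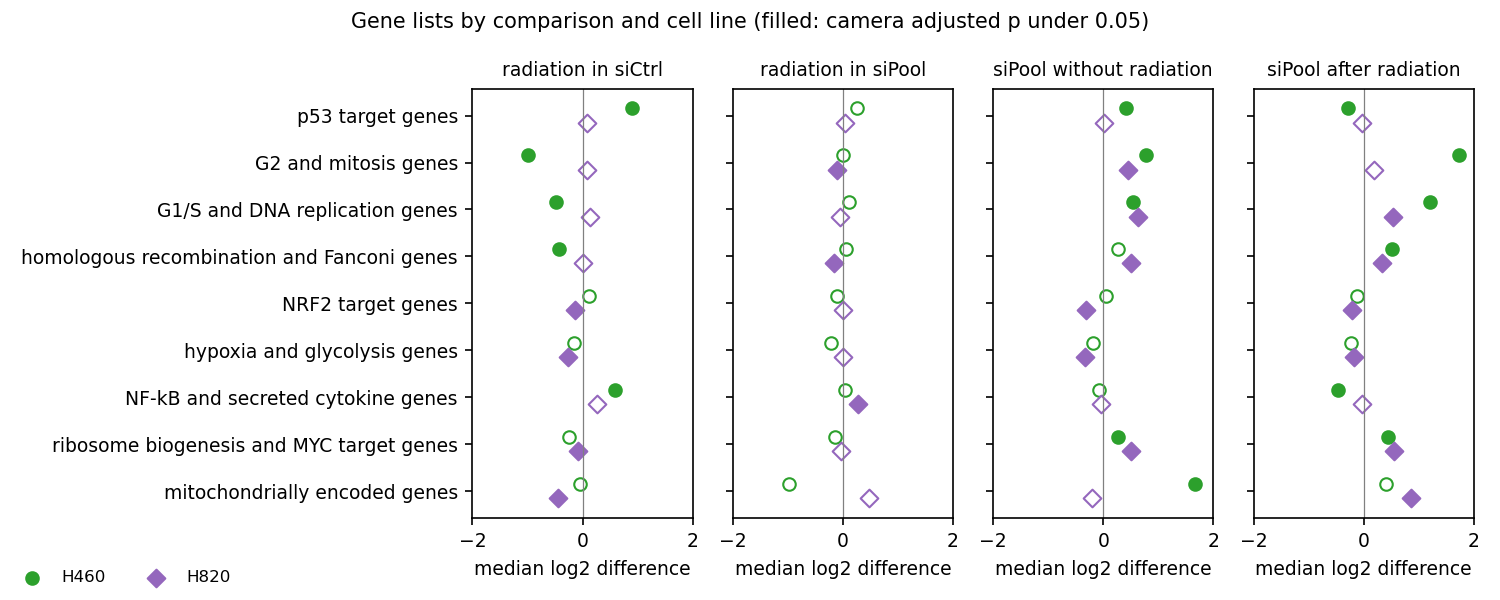
Median log2 difference of 9 gene lists (horizontal axis, 1 panel per comparison) in H460 (circles) and H820 (diamonds), filled where the camera adjusted p was under 0.05. For radiation in siCtrl the p53 target genes lay at 0.90 in H460 and at 0.09 in H820.

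Between the lines, 13002 genes were tested in both, and fold changes across these genes had a Pearson r of 0.07 for radiation in siCtrl, 0.17 for siPool without radiation, 0.14 for siPool after radiation, -0.01 for radiation in siPool and 0.03 for the interaction. No gene was called in both lines in any comparison by edgeR in H460 and limma in H820, since edgeR called 0. The 7 genes lower with siPool in H820 had changes between -0.60 (B3GNT5, SE 0.596) and 0.16 (PLOD2, SE 0.551) in H460 siPool without radiation, none past the test. Within H460 the siPool effects with and without radiation had a Pearson r of 0.06, and the radiation effects with and without siPool a Pearson r of 0.01, where the pair labelled siPool C enters both; in H820 the latter was 0.26.

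Some lists were not called in either line or in 1 of them. In H460 the camera adjusted p over the 5 comparisons ran from 0.142 to 0.895 for non-homologous end joining genes, 0.235 to 0.824 for interferon-stimulated genes, 0.201 to 0.898 for epithelial-mesenchymal transition genes, 0.0597 to 0.898 for apoptosis regulators, 0.0976 to 0.68 for NRF2 target genes and 0.0787 to 0.665 for hypoxia genes. Of the markers of other cell types it ran from 0.439 to 0.993 for fibroblast and endothelial genes, 0.665 to 0.996 for leukocyte genes, 0.0695 to 0.898 for neuroendocrine genes and 0.299 to 0.898 for alveolar genes. Small structural RNAs had 0.077 to 0.771. In H820 the range was 0.159 to 0.799 for end joining (fry gave an adjusted p of 0.0128 for siPool without radiation, with 13 of 17 positive), 0.783 to 0.998 for epithelial-mesenchymal transition, 0.171 to 0.854 for ATF4, 0.329 to 0.859 for p53 target, 0.1 to 0.919 for fibroblast and endothelial and 0.0731 to 0.919 for leukocyte genes. Histone genes and small structural RNAs had 0 tested genes in H820 and neuroendocrine markers 2, under the minimum of 5.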

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

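The tests of library complexity, of a pool effect on p53 target genes, of the order number, and all splits of libraries into other groups were chosen only after the results were seen.

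The radiation effect differed between siPool and siCtrl, by camera on the interaction, for 12 gene groups, with 0 groups marked by an untested difference. In H460 the median differences were -0.628 for p53 target genes, 0.972 for G2 and mitosis genes, -0.257 for unfolded protein response genes, -0.445 for cholesterol synthesis genes, -0.19 for autophagy and lysosome genes and -1.01 for mitochondrially encoded genes. Each used the libraries labelled siPool NR C and siPool 8gy C. In H820 they were -0.22 for G2 and mitosis genes, -0.202 for G1/S genes, -0.185 for unfolded protein response genes, 0.226 for hypoxia genes, 0.364 for alveolar markers and 1.0 for mitochondrially encoded genes. The mitosis and mitochondrial groups had opposite signs in the 2 lines with all libraries; without the library labelled siPool NR C the H460 mitochondrial median was 0.696, and the signs were then the same. None of the 12 held with an estimated correlation (adjusted p 0.862 in H460, 0.532 to 0.621 in H820).

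The p53 target genes of the libraries labelled H460 siPool NR C and siPool 8gy C lay opposite to their labels, at 1.17 and -0.34. An exchange of the labels could give this, and was tested over 643 genes outside the list. They had an unadjusted edgeR p under 0.05 for radiation in siCtrl. With 653 such genes in all where chance gives 871, many may carry no radiation effect. Over them, the library labelled siPool 8gy C minus that labelled siPool NR C had an r of -0.24 with the radiation effect in siCtrl. The same r was 0.12 for B but -0.03 for A, so the bound set beforehand, positive in both, was not met and the question stays open. All 5 H460 libraries with more genes at 0 lay on the side of their labels, a test that replaced one that had not decided. It decides nothing about low complexity, since the pair was picked as the libraries opposite to their labels. The share of genes at 0 was 21.1% in the library labelled siPool NR C and 31.6% in that labelled siPool 8gy C. The other 10 had a median of 31%, so by this share neither stood out as of low complexity. On the p53 target genes siPool NR A and B had a median of -0.246 against siCtrl NR, so these 2 libraries showed no rise. Their scores were known when the pair was singled out, so this does not decide about a pool effect.

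Of the genes lower with siPool in H820, all passed with the order number as a block, a count of 7 that decides nothing about that order: each number held all 4 groups, so the block could not move the fold. Without the order 01 libraries, which are letter A, their median change was -1.91, so the lowering was also present in letters B and C. The genes had been called over all letters, with every siPool library below every siCtrl library. A lasting fold was therefore likely and does not decide about order 01. Loss of lnc-RAINY, another effect of the siRNA pool, or culture density remain open, since 1 pool and 1 control do not separate them; in H460 the same genes had a median of -0.17.

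edgeR called no H460 gene for radiation in siCtrl (DESeq2 25) although the p53 target genes as a group lay higher. Leaving out the 3 libraries that stood apart gave 1 gene, MEST, with a biological coefficient of variation of 0.663 against 0.845, which leaves their part undecided. The spread between libraries might be too large for 3 per group, as 30.5% of simulated 4-fold changes were called, a value between the bounds set beforehand.

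Libraries were also split into other groupings: every one for 3 against 3 libraries, and a random draw for the interaction. With 10 splits per comparison of 3 against 3 libraries, the splits are too few for a share under 0.05. In H460 the real count of 0 was met by 10 of 10 splits in each of these 4 comparisons, and the highest other count was 0 except for radiation in siPool, where it was 11. That split set siPool NR A, siPool NR B and siPool 8gy C against the rest, a structure of these samples that follows the p53 target genes. An exchange of the labels siPool NR C and siPool 8gy C would give this grouping. That pair had been picked by its p53 target genes, so the count does not decide about an exchange. In H820 radiation in siCtrl had 0 genes with the real labels, met by 10 of 10 splits, and 294 with siCtrl NR A, siCtrl 8gy A and siCtrl 8gy C against the rest, so these samples have a structure other than radiation. For siPool without radiation the real count of 7, and after radiation of 2, was reached by 1 of 10 splits, the real one, with 0 in the others. Radiation in siPool had 0, reached by 10 of 10. For the interaction the real count of 0 was reached by 60 of 60 drawn splits in H460 and 100 of 100 in H820, where the highest other count was 1. Every split reaches a count of 0, so the shares at a real count of 0, here and above, decide nothing. The splits counted include the real one.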

How the results depend on the processing

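The fits without the pair labelled siPool C, without the 3 libraries apart, with quality weights and on recovered reads, and the list tests with libraries left out, were chosen only after the data were seen. The 7 lower genes of H820 siPool without radiation kept their direction. Their calls, like the list calls, depended on the libraries included, and LYN passed in 0 of 9 fits with a library or letter left out. List calls also depended on the correlation assumed between genes.

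For H460 radiation in siCtrl, 0 genes became 25 with DESeq2, 3 with limma-voom and quality weights together and 1 without the 3 libraries apart. Without the pair labelled siPool C it was 1, the p53 target gene GDF15, and p53 target scores had picked out that pair. Of 9 lists 0 were called with an estimated correlation and 0 with fry. For siPool without radiation, 0 genes became 11 with DESeq2, 5 with no filter, 50 with limma-voom and quality weights together and 22 without the 3 apart; of 5 lists 0 held with an estimated correlation, 0 with fry and 0 without the pair, and 10 were called without the 3 apart. Leaving out libraries gave 0 to 6 genes and 0 to 10 lists. For siPool after radiation, 0 genes became 34 with DESeq2; of 9 lists 0 held with an estimated correlation and 0 with fry, 4 were called without the pair, and leaving out libraries gave 0 to 9 genes and 4 to 12 lists. For radiation in siPool, 0 genes became 22 with DESeq2 and 1 without the pair, and 0 lists became 4 without the pair (picked out by p53 target scores, so not a test of them), 3 without the 3 apart and 2 to 6 with libraries left out. For the interaction, 0 genes became 21 with DESeq2; of 6 lists 0 held with an estimated correlation, 0 with fry and 0 without the pair, 10 were called with the replicate block, and leaving out libraries gave 0 to 10. The replicate block called 0 genes in each H460 comparison.

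For H820 radiation in siCtrl, 0 genes became 1 with no filter; of 7 lists 0 held with an estimated correlation and 0 with fry, and leaving out libraries gave 0 to 6. For siPool without radiation, 7 genes became 13 with the replicate block, 21 with the block and quantile normalization, 20 with edgeR on recovered reads and the block, and 0 with only the groups compared; leaving out libraries gave 0 to 16. Of 9 lists 1 held with an estimated correlation; fry called 5 lists, 4 of these 9 and non-homologous end joining. For siPool after radiation, 2 genes became 1 with quantile normalization, 5 with the block and quantile normalization, 5 with edgeR on recovered reads, 12 with edgeR and the block, and 0 with only the groups compared; leaving out libraries gave 0 to 166 genes and 4 to 12 lists. Of 10 lists 0 held with an estimated correlation and 1 with fry. For radiation in siPool, of 6 lists 0 held with an estimated correlation and 0 with fry, and leaving out libraries gave 1 to 8. For the interaction, 0 genes became 1 with no filter; of 6 lists 0 held with an estimated correlation and 0 with fry, and leaving out libraries gave 0 to 8.

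Sample quality weights were also tried in H820 and are not used: the weights did not converge (22.3 and 47.9 for siCtrl 8gy C and siPool 8gy C), and the counts seen were 5233 for radiation in siCtrl, 435 for siPool without radiation, 10795 for siPool after radiation, 0 for radiation in siPool and 1792 for the interaction. Fold changes from limma on log2 RPKM in both lines had an r between lines of 0.12, 0.18, 0.26, 0.02 and 0.09 in the order radiation in siCtrl, siPool without radiation, siPool after radiation, radiation in siPool and interaction. A limma fit over all 24 libraries was not run, since no table held both lines.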

Other observations

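The genes and fits below were chosen only after the results were seen. DESeq2 called genes in H460 where edgeR called none. For radiation in siCtrl they included TGFBR1, a TGF-beta receptor (1.82, adjusted p = 0.000295), and NRG1, a ligand of ERBB receptors (2.12, adjusted p = 0.0123), higher, and CEBPD, a transcription factor (-2.30, adjusted p = 0.000144), lower. For siPool without radiation they included NT5E (-2.13, adjusted p = 0.000814) and PLAT, a plasminogen activator (-1.90, adjusted p = 0.00355), and for siPool after radiation BLM (2.45, adjusted p = 0.000825). The directions with siPool use the pair labelled siPool C.

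Without the libraries siPool NR A, siPool 8gy A and siCtrl 8gy B, edgeR called 22 genes for H460 siPool without radiation. The immediate early gene EGR1 was higher (2.37, adjusted p = 0.00295), as was MEST, an imprinted gene (2.26, adjusted p = 0.0085), and PAEP (-3.21, adjusted p = 0.00177) and NTSR1, a neurotensin receptor (-2.51, adjusted p = 0.00197), were lower. Without the pair labelled siPool C, edgeR called GDF15 for radiation in siCtrl (2.53, SE 0.36, adjusted p = 0.0431). GDF15 is on the p53 target list, whose scores had picked out that pair. The pair lies in neither siCtrl group, so leaving it out acts mainly on the spread shared by all groups. This call is therefore no separate evidence.

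In H820 siPool without radiation, the NF-kB list was called only with the replicate block. Adjusted over the list alone, without the block, 4 of its genes were lower: ICAM1, an adhesion receptor (-1.34, adjusted p = 0.0162), IGFBP3, which binds insulin-like growth factors (-1.0, adjusted p = 0.034), the chemokine CCL20 (adjusted p = 0.0437) and the matrix protease MMP10 (adjusted p = 0.0437). The interleukin receptor IL7R was the 1 higher (0.80, adjusted p = 0.0437). Over all genes 0 of the list passed.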
